A study of Geobacter sulfurreducens with 3 samples.

How the data were processed

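Genomic DNA of *Geobacter sulfurreducens* PCA was measured after growth on Fe(III) citrate, HFO or fumarate, with 1 library per acceptor. Per the labels, HFO cultures were dissolved with oxalate before DNA extraction, while cells of the other cultures were spun down directly, so this step differed together with the acceptor. The labels speak of libraries of replicates and do not say whether cultures were pooled. Per the labels, the authors sequenced on a PacBio RS to a mean depth above 175 reads per genome position, mapped reads with BLASR (version not given in the sources used here) to a reference sequence of strain PCA, and detected modifications with SMRTPipe 1.3.3 against an in silico model of unmodified DNA. Each deposited table lists positions with their type (m6A or m4C), coverage, IPD ratio, identification score, the 41 bases around them and the gene they fall in. The labels and a line of the tables name different records of the chromosome, which were taken to be the same sequence.

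The deposited coverage is a signal, the number of reads over the position, in whole numbers and not scaled between libraries. It was read as coverage of 1 strand, since kinetics are measured per strand; doubled, its medians are 170, 222 and 212 for Fe(III) citrate, HFO and fumarate. The deposited IPD ratio is a ratio of the mean inter-pulse duration to that of the model. The deposited identification value is a score, a whole number that states how firmly the type of modification was identified and that grows with coverage. Per the labels the authors kept positions with coverage above 25 and a quality value above 30, where that value came from the test of sample against model. That value is not among the columns used here, so the same thresholds were applied to the identification score. This choice can lose positions, since identification scores in the tables went down to 3, and it makes the number of calls depend on coverage. Only 20, 1 and 2 listed positions of Fe(III) citrate, HFO and fumarate had coverage of 25 or less. A stray line of another format was skipped in the Fe(III) citrate table and another in the fumarate table.

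The tables give no strand and no genome sequence was used. The sequence was therefore rebuilt from the overlapping 41-base contexts, which also gave each position its strand. This covered 3748915 of 3814128 bp (98.3%) without a disagreement between contexts, and the strand stayed open for 338 of 667866 positions. As a check on the coordinates, 3250 of 3257 gene starts (99.8%) read ATG, GTG or TTG. Words and shares of bases were counted in the rebuilt sequence; 3 m6A calls per library lay in GTACAG by their own context at positions with open strand and are not among the 736 occurrences. Genes, their ends and products came from the tables (3429 genes), with symbols for 771 of them and the places of RNA genes from a table of the current RefSeq annotation, matched by locus tag for 3366 genes.

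Calls were counted per library with exact Poisson intervals, and shares with Wilson intervals. The number of positions shared by a pair of libraries was set against that for independent lists of the same length within each base. Words of 4 to 6 bases and gapped words of 3 and 3 bases with 4 to 8 free bases between were taken from the 1000 calls of highest score per library and type. They were ranked by the share of their occurrences called and reported when 50% of at least 50 occurrences were called in 1 library, then lengthened by single bases while the share grew. The search planned for G and T found no call of these bases. Location was compared as the share of cytosines or adenines called in coding sequence, in the 200 bp upstream of a gene outside genes, and in the rest, over the genome's share. Gene groups were fixed by product words or locus tags before the data were examined. For each the median over genes was ranked among 10000 random lists of equal size, matched on GC content in 10 classes and not on gene length, which entered only through calls per kb. A percentile says how unusual a list is among genes of 1 library or pair, not whether an acceptor has an effect.

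Ratios between libraries were scaled by the library's total of calls, and their intervals come from the exact binomial (Clopper-Pearson) interval of the split of calls. A gene was compared with at least 20 calls in the pair. A gene with 0 calls in 1 library was ranked by a floor of 3 calls per library; no fold is given for such genes, since those named lie where the library listed no position. Neighbouring calls are not independent, so these intervals are the least the error can be. Local coverage of a position was the median of listed positions around it. The adjustment for local coverage took the residual from a straight line, fitted over genes, of the log2 ratio of calls on the log2 ratio of coverage, with slopes of 1.84, 1.93 and 1.39 for HFO over Fe(III) citrate, fumarate over Fe(III) citrate and HFO over fumarate. Slopes above 1 mean that calls changed more than coverage did. Genes without a listed position in 1 library had no coverage ratio and kept their unadjusted ratio.

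Genes were named by a rule fixed before the data were examined: per pair, the 5 highest and 5 lowest log2 ratios, the listed genes of extracellular electron transfer, fumarate use and DNA methyltransferases, and, of GTACAG sites, the 5 with the largest difference in IPD ratio per pair and those in the listed genes. Sites not called in all libraries, GSU2128, GSU2140 and the other genes of the unlisted stretch were named after their values were seen. Alternatives were other score and coverage thresholds, calls by IPD ratio, scores scaled to equal coverage, equal list lengths, other upstream lengths, gene bodies or upstream parts alone, scaling by the median ratio and, chosen after the data were seen, matched or adjusted local coverage and leaving out the genes of the stretch. Calls by IPD ratio needed a ratio of at least 2, a score over 20 and coverage over 25, so they still depended on coverage through the score.

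The steps were tested on simulated data. With 200 changed genes planted for HFO over Fe(III) citrate among 3429, the interval lay on the right side of 0 for 96.0% of genes raised 2-fold, 86.0% of those lowered 2-fold and 100% of those changed 4-fold. It excluded 0 for 5.84% of unchanged genes. The planted genes had at least 20 calls on Fe(III) citrate. Calls were drawn independently in gene bodies alone, without differences of coverage, so these rates do not cover errors that come from coverage. Of random lists without an effect 5.00% lay outside the central 95%. These lists were drawn in the same way as the reference lists, so this checks the program and not the ranking of real groups. A planted word was found first. The programs were written in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.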

Results

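Genomic DNA of *Geobacter sulfurreducens* PCA, an anaerobic bacterium that respires iron oxides through multiheme cytochromes, was sequenced by single-molecule real-time (SMRT) sequencing after growth on 3 electron acceptors. The cultures oxidised 20 mM acetate at 30 °C and pH 6.8 with 50 mM Fe(III) citrate, 50 mM hydrous ferric oxide (HFO, a solid iron oxide) or 40 mM fumarate, and were taken in mid-exponential phase. Each acceptor had 1 library, so no value below has a replicate error and no test between acceptors was possible; intervals are 95% and cover counting error only. SMRT sequencing reads modified bases from the inter-pulse duration (IPD), the time the polymerase takes between 2 incorporations, given as a ratio to that of unmodified DNA. The tables listed positions typed as N6-methyladenine (m6A) or N4-methylcytosine (m4C), 291159 for Fe(III) citrate, 493565 for HFO and 381972 for fumarate. Median coverage of a listed position was 85 reads on its strand for Fe(III) citrate, 111 for HFO and 106 for fumarate. A position was called here when its identification score was above 30 and its coverage above 25. Positions outside the tables have no value and were counted as not called, not as unmethylated. Coordinates are those of the tables, on the 3814128 bp chromosome of strain PCA.

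The first comparison asked which adenines were methylated and whether this changed with the acceptor. Methylation of the adenine at base 5 of the word GTACAG was close to complete in all 3 libraries. Of 736 GTACAG occurrences, 99.0% (Wilson interval 98.0 to 99.5%) were called on Fe(III) citrate, 99.7% (99.0 to 99.9%) on HFO and 99.3% (98.4 to 99.7%) on fumarate. Their median IPD ratio was 7.25, 6.75 and 7.03. GTACAG was the highest of 1228 words searched around adenines; the next, TACAGG, which contains most of the same bases, reached 45.4%. The sites lay in genes in 663 cases, spread over 557 genes, in the 200 bp upstream of a gene in 52 and elsewhere in 21, with 373 on the plus strand and 363 on the minus strand. Their density was 0.192 per kb (Poisson interval 0.177 to 0.207) in coding sequence and 0.208 per kb (0.156 to 0.273) upstream of genes, a difference within the counting intervals. The textbook adenine words were almost free of calls. GATC was called at no more than 0.0159% of its 44006 occurrences and GANTC at no more than 0.165% of 21814, in any library.

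Of the genes of extracellular electron transfer and fumarate use listed before the data were examined, cbcL and ompB held 2 GTACAG sites each, and ppcD, omcS, omcB, frdC and frdB held 1 each. The product of cbcL is an inner membrane cytochrome, ppcD encodes a periplasmic cytochrome, and omcS and omcB encode outer surface cytochromes. The genes frdC and frdB encode subunits of the fumarate reductase, which also works as succinate dehydrogenase, and ompB encodes a multicopper oxidase. All 9 of these sites were called in every library. The frdC site at 1282159 had IPD ratios of 10.0 on Fe(III) citrate, 8.96 on HFO and 10.2 on fumarate. At the omcS site at 2759060 the ratios were 7.67, 5.06 and 5.83, and at the omcB site at 3014923 they were 5.53, 4.83 and 4.2. The ompB site at 1531015 went the other way, with 4.69 on Fe(III) citrate, 5.34 on HFO and 7.65 on fumarate. So did the other ompB site, at 1534239 (3.11, 3.43 and 3.49), and the ppcD site (2.43, 2.56 and 3.07). The cbcL sites had 4.89, 4.16 and 4.25 at 283046 and 10.36, 9.87 and 8.31 at 284703. At the frdB site the ratios were 3.84, 3.49 and 4.48, so the 9 sites had no common direction. Over all GTACAG sites the log2 ratio between 2 libraries had an SD of 0.24 to 0.27 across sites. Across the 16 gene groups fixed before the data were examined, no group's density of GTACAG sites lay outside the central 95% of 10000 random gene lists matched on GC content. The 113 genes of c-type cytochromes came nearest, with 42 sites, 0.265 per kb, at percentile 96.1.

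At the score threshold of 30, nearly the same GTACAG sites were called with each acceptor. In total 726 of the 736 sites (98.6%) were called in all 3 libraries, and 10 were not. Of these 10, 3 lay in a stretch for which the fumarate table listed nothing, described below, at 2348477 upstream of GSU3559 and at 2353957 and 2354344 in the efflux pump gene GSU2136. A further site, at 2357112 in the transposase gene GSU2140 of the insertion sequence ISGsu7, was listed on fumarate only. Fe(III) citrate and HFO listed 0 positions in that whole gene, so the site has no value in them. The other 6 were listed in all 3 libraries with IPD ratios between 1.99 and 10.2 and missed the call through the score or the coverage. They lay upstream of GSU0772, a flavodoxin gene, upstream of GSU1845, and in GSU1611 (an efflux pump gene), GSU1924, GSU2038 (the type IV pilus gene PilY) and GSU2073. The site upstream of GSU1845, at 2017115, was called in none of the libraries although its IPD ratio was 9.97, 7.3 and 10.2, and the GSU2073 site had 17 reads on Fe(III) citrate. No site listed in 2 libraries differed between them by 2-fold or more in IPD ratio. At a score over 100, where calls are far from complete, 65.2%, 87.5% and 85.7% of sites were called and 320 were not called in all 3 libraries.

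Site by site, the IPD ratios at GTACAG followed each other between libraries. Pearson's r across sites was 0.78 for HFO and Fe(III) citrate (735 sites), 0.76 for fumarate and Fe(III) citrate (732 sites) and 0.81 for HFO and fumarate (732 sites), with Spearman's rho of 0.763, 0.762 and 0.796; sites of 1 library are not independent replicates. The median ratio of IPD ratios was 0.928 for HFO over Fe(III) citrate, 0.969 for fumarate over Fe(III) citrate and 0.962 for HFO over fumarate. The 5 largest differences between HFO and Fe(III) citrate were all lower on HFO and lay in GSU1035 (a chemotaxis receptor, 6.35 against 11.8), GSU1745 (7.19 against 12.4), ptsP (9.47 against 14.1), GSU0714 (9.54 against 14.04) and GSU1870 (a diguanylate cyclase, 8.6 against 12.8). Coverage at these sites, in the same order, was 111, 122, 73, 129 and 120 on HFO and 67, 70, 88, 75 and 75 on Fe(III) citrate. Between fumarate and Fe(III) citrate the largest were in ptsP (8.93 against 14.1), gmd (GDP-mannose dehydratase, 12.8 against 7.78), GSU1870 (8.17 against 12.8), serA (D-3-phosphoglycerate dehydrogenase, 12.1 against 7.66) and GSU0168 (9.14 against 13.4). Between HFO and fumarate they were in gmd (7.82 against 12.8), rsmI (8.04 against 12.1), GSU0874 (7.71 against 11.8), serA (8.22 against 12.1) and GSU2511 (6.1 against 9.63).

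**Figure D1:**
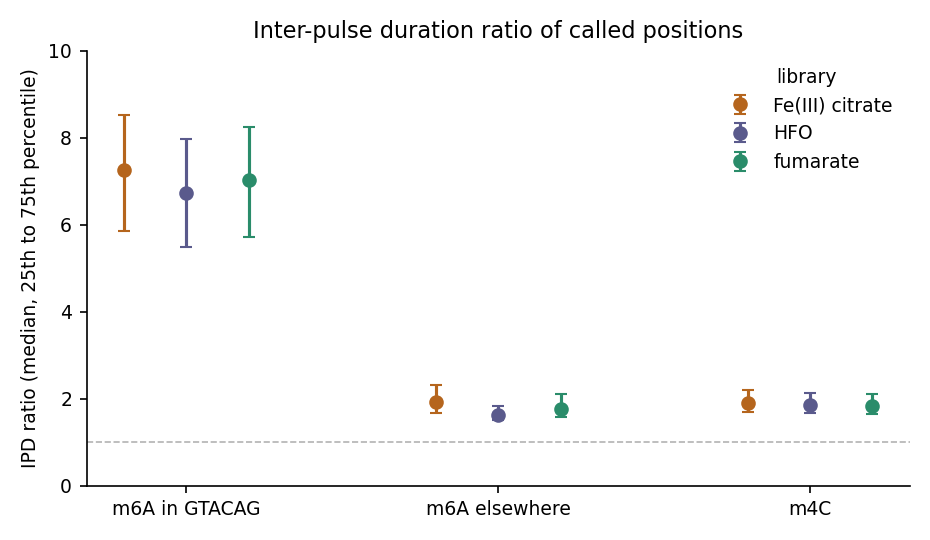
Median IPD ratio of called positions by class and library, with bars from the 25th to the 75th percentile; the y axis is a ratio without unit and the dashed line marks 1. The m6A calls in GTACAG lie near 7 in all 3 libraries, while the other m6A calls and the m4C calls have medians below 2.

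The m6A calls outside GTACAG formed a second class with much lower IPD ratios. The libraries had 1829 m6A calls on Fe(III) citrate, 1757 on HFO and 2095 on fumarate, of which 1097, 1020 and 1361 lay outside GTACAG. Their median IPD ratio was 1.92, 1.63 and 1.76. An IPD ratio of 4 or more was seen at 93.9%, 92.3% and 92.8% of the calls in GTACAG, but at 14, 0 and 8 of those outside it. Any pair of libraries still shared many of these positions: HFO and Fe(III) citrate shared 339, 33.2% of the shorter list, fumarate and Fe(III) citrate 542 (49.4%), and HFO and fumarate 409 (40.1%), where independent lists would share about 1. The word GAGGYAGYA (Y is C or T), chosen after its values were seen, was called at base 2 at 61.3% (50.3 to 71.2%), 46.3% (35.7 to 57.1%) and 72.5% (61.9 to 81.1%) of its 80 occurrences. Its median IPD ratio was 2.6 on Fe(III) citrate, 2.13 on HFO and 2.43 on fumarate.

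The next comparison asked how m4C differed between acceptors. HFO had the most m4C calls, 335586 or 14.6% of the cytosines of both strands. Fumarate followed with 237309 (10.3%) and Fe(III) citrate with 151331 (6.60%). The ratios of the calls were 2.22 for HFO over Fe(III) citrate, 1.57 for fumarate over Fe(III) citrate and 1.41 for HFO over fumarate, and the ratios of median coverage ran the same way, at 1.31, 1.25 and 1.05. The ratios depended on the threshold: they were 4.84, 2.67 and 1.81 at a score over 100. They were 1.799, 1.198 and 1.502 with calls taken by an IPD ratio of at least 2 at a score over 20. Among cytosines at a local coverage within 5 reads of 100, the share called was 8.97% (8.88 to 9.07%) on Fe(III) citrate, 12.9% (12.8 to 13.0%) on HFO and 9.40% (9.33 to 9.47%) on fumarate. At that coverage HFO exceeded Fe(III) citrate 1.43-fold (1.42 to 1.45) and fumarate 1.37-fold (1.35 to 1.38), and fumarate exceeded Fe(III) citrate 1.05-fold (1.03 to 1.06). The m4C calls had a median IPD ratio of 1.91, 1.86 and 1.84 on Fe(III) citrate, HFO and fumarate, and 3.36%, 1.35% and 1.99% of them reached 3. Applied to the numbers of calls, these shares leave no excess on HFO among calls with an IPD ratio of 3 or more.

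**Figure D2:**
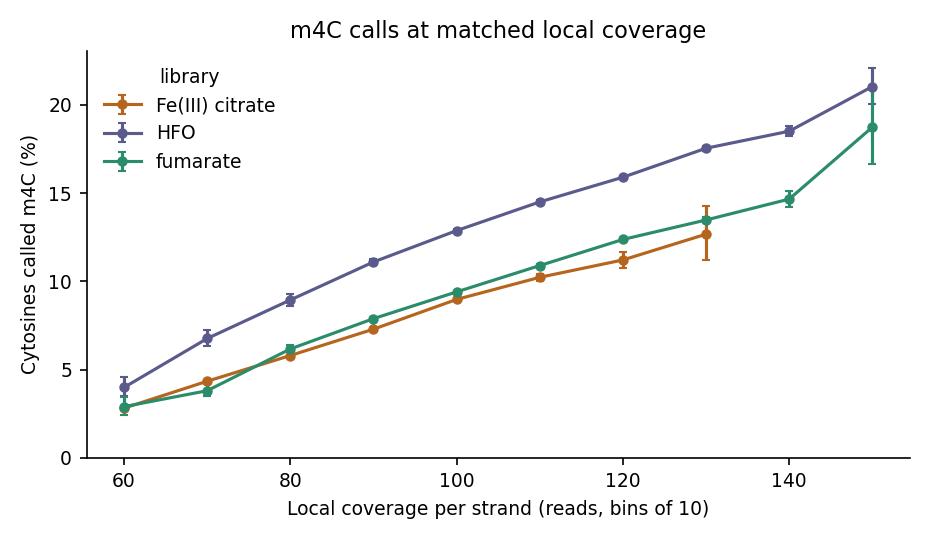
Percent of cytosines called m4C (y axis) against local coverage per strand in reads (x axis, bins of 10) for each library; points are shares and bars their 95% Wilson intervals. The share rises with coverage in all 3 libraries, and within 5 reads of 100 it is 12.9% on HFO against 8.97% on Fe(III) citrate and 9.40% on fumarate.

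Many m4C positions recurred. HFO and Fe(III) citrate shared 102859 positions, 68.0% of the shorter list and 4.65 times the number for independent lists. Fumarate and Fe(III) citrate shared 92388 (61.1%, 5.90 times) and HFO and fumarate 152505 (64.3%, 4.39 times). All 3 libraries shared 73433. The m6A calls shared by all 3 numbered 982.

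The m4C calls followed the bases around the cytosine, and no short word was called completely. Cytosines in GCG were called at 21.1% on Fe(III) citrate, 34.3% on HFO and 29.5% on fumarate, and those in ACA at 0.549%, 1.83% and 1.05%. Cytosines before a G were called at 12.3%, 24.6% and 18.7%, and the other cytosines at 4.07%, 10.2% and 6.64%. Of 1333 words searched, GGCGCC at base 3 was the highest, with 41.8% of its 6920 occurrences called on Fe(III) citrate, 64.6% on HFO and 55.5% on fumarate, and 12 words reached 50% in at least 1 library. Most of the 12 held GGCGC, GCGCC or CGCCG. Lengthening a word base by base while its share grew led to GGCGCCGACA, called at 74.0%, 94.0% and 86.0% of 50 occurrences, and to GCGCCAGTT, at 86.9%, 93.4% and 93.4% of 61; these are the highest of many words tried. The word CCWGG (W is A or T), methylated in many bacteria, was called m4C at no more than 6.85% at its first cytosine and 11.7% at the next, both on HFO. Only m4C and m6A were typed, so these shares do not say whether CCWGG carried another modification.

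Calls were unevenly placed relative to genes. In the 200 bp upstream of genes the share of cytosines called m4C was 0.688 times the genome's on Fe(III) citrate (0.670 to 0.706), 0.716 times on HFO (0.704 to 0.728) and 0.697 times on fumarate (0.683 to 0.711). In coding sequence the same ratio was 1.03, 1.02 and 1.03. In the other intergenic sequence it was 0.70, 0.72 and 0.68, so the low share was not particular to upstream sequence. The shares were matched on the base and not on the bases around it, which the calls followed. For m6A the upstream ratio was 0.952 (0.792 to 1.13), 0.983 (0.817 to 1.17) and 0.985 (0.832 to 1.16), so no difference was detectable at these counts. The ribosomal RNA genes had 22.7 calls of both types per kb on Fe(III) citrate, 60.03 on HFO and 42.3 on fumarate, against 40.2, 88.4 and 62.8 for the genome. The 48 transfer RNA genes had 34.5, 89.3 and 56.4.

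The design then compared 16 gene groups, counting calls of both types in the gene and the 200 bp before it. The c-type cytochromes, a list of 113 genes that includes biogenesis factors, carried few calls for their GC content on HFO and fumarate. Their median was 80.3 calls per kb on HFO (percentile 0.03 of the random lists) and 54.7 on fumarate (percentile 0.02); on Fe(III) citrate it was 36.04, at percentile 5.21. The 59 genes matched by ribosomal protein had 35.7, 79.3 and 51.0 calls per kb on Fe(III) citrate, HFO and fumarate, fewer than the genome as a whole but at percentile 99.7 or above among lists of the same GC content. The 36 transposase and integrase genes, also below the genome's density, had 36.4 per kb on Fe(III) citrate (percentile 99.7 of such lists), 86.3 on HFO (percentile 100) and 51.2 on fumarate (percentile 95.8). The 76 chemotaxis and flagellar genes had 96.3 calls per kb on HFO (percentile 99.9) and the 15 DNA repair genes 110 (percentile 99.1). The 23 genes matched by terms of the TCA cycle and acetate oxidation had 29.5 on Fe(III) citrate (percentile 2.39). That list also holds nifV (trans-homoaconitate synthase) and leuB (3-isopropylmalate dehydrogenase), matched by words in their products. The 11 ATP synthase genes had 65.1 calls per kb on fumarate (percentile 99.9). In the other libraries the chemotaxis, DNA repair, TCA cycle and ATP synthase groups lay within the central 95%. On HFO the TCA cycle genes were at percentile 61.1 and the ATP synthase genes at 10.4. Over 16 groups and 3 libraries, 11 densities lay outside the central 95% of the random lists, but 7 did with calls by IPD ratio and 6 with upstream sequence alone.

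Between libraries, after scaling by each library's total, 3 of 48 group ratios lay outside it. Each pair had 1 of its 16 ratios outside, where chance alone would give 0.8. Over densities and ratios together 14 of 96 did, against 4.80, so the excess lay in the densities, which were not adjusted for coverage. The 96 values are not independent, and genes of a group often lie side by side, unlike those of random lists. The numbers for chance are therefore only a guide. The ATP synthase genes, which encode the enzyme that forms ATP from the proton gradient, had relatively few calls on HFO. Their median log2 ratio was −0.30 for HFO over Fe(III) citrate (percentile 1.87) and −0.45 for HFO over fumarate (percentile below any random list), with 2 and 4 of the 11 genes below 0 by their counting interval and none above. The c-type cytochromes had a median of −0.18 for fumarate over Fe(III) citrate (percentile 0.02), with 24 of the 113 genes below 0 and 14 above. Local coverage differed in the same direction in these genes, with percentiles of its ratio of 0.755, 0.01 and 0.095. After adjustment for local coverage, chosen after the values were seen, the medians were −0.04 (percentile 38.8), −0.07 (percentile 17.4) and −0.09 (percentile 3.50).

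**Figure D3:**
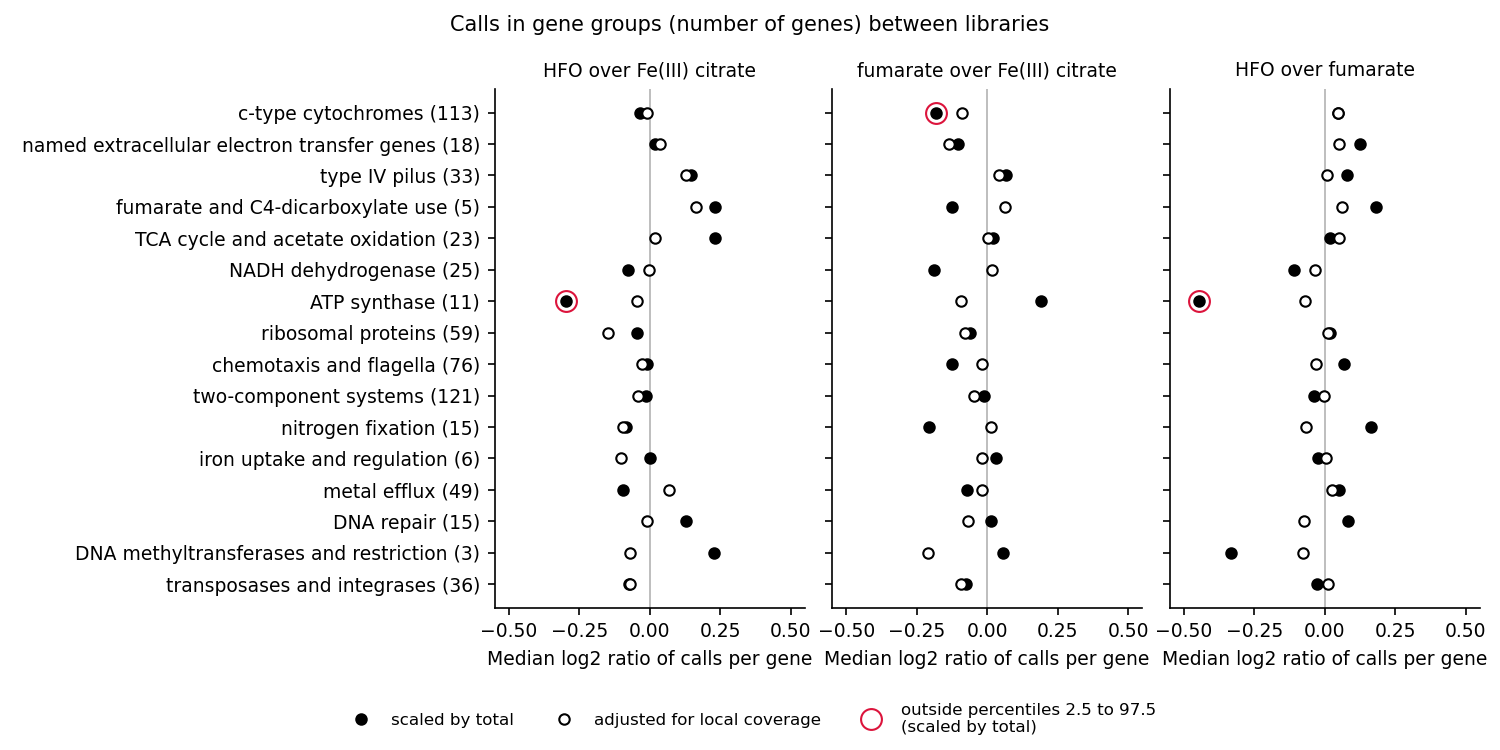
Median log2 ratio of calls per gene in 16 gene groups (number of genes in parentheses) for the 3 pairs of libraries; filled points are scaled by the library totals, open points are also adjusted for local coverage, and red rings mark the 3 medians outside the central 95% of random lists. The ringed ATP synthase medians of −0.30 and −0.45 move to −0.04 and −0.07 with the adjustment.

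The other groups had no ratio outside the central 95%. The 33 genes matched by type IV pilus terms, which include pseudopilins of type II secretion, had 0.15 for HFO over Fe(III) citrate, 0.07 for fumarate over Fe(III) citrate and 0.08 for HFO over fumarate, and 8 members lay above 0 and none below in the last pair. The 18 named genes of extracellular electron transfer had 0.02, −0.10 and 0.13. The 5 genes of fumarate and C4-dicarboxylate use had 0.23, −0.13 and 0.18, the 25 NADH dehydrogenase genes −0.08, −0.19 and −0.11, and the 121 two-component system genes −0.01, −0.01 and −0.04. Nitrogen fixation (15 genes) had −0.08, −0.21 and 0.17, iron uptake and regulation (6 genes) 0.00, 0.03 and −0.02, and the group of efflux and heavy metal transport genes (49 genes, many of them pumps with no named metal) −0.09, −0.07 and 0.05.

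For single genes, HFO and Fe(III) citrate were compared over 3378 genes with at least 20 calls in the pair. The scaled number of calls differed by more than 2-fold in 225, higher on HFO in 198 and lower in 27. In data simulated from counting error alone, and for gene bodies only, 67 of 3015 unchanged genes did so. The highest log2 ratios lay beside each other in GSU2074, a peptidylprolyl isomerase gene at 2278900 to 2279865 (112 calls on HFO and 1 on Fe(III) citrate, log2 ratio 5.67, interval 3.16 to 10.99), and GSU2075, a subtilase protease gene (174 and 6 calls, 3.72, interval 2.57 to 5.19). Median coverage there was 102 and 109 on HFO but 26 and 35 on Fe(III) citrate, and adjusted for local coverage, an adjustment chosen after the values were seen, the ratios were 2.67 and 1.34. The next, GSU1318, GSU3538 and the endonuclease gene GSU2070, had 19 to 21 calls on HFO and 1 on Fe(III) citrate, with adjusted ratios of 2.63, 2.59 and 2.63. The intervals of their unadjusted ratios were wide, 0.62 to 8.62, 0.54 to 8.56 and 0.46 to 8.49, and the adjusted ratios have no interval. Coverage of these genes was 94, 108 and 95 on HFO and 58.5, 68 and 62.5 on Fe(III) citrate. The lowest were the transposase gene GSU2396 (20 and 32 calls, −1.82, interval −2.70 to −0.97), GSU2398 (−1.76), the lipoprotein gene GSU0852 (−1.63), GSU2395 (−1.55) and GSU3579 (−1.52). Of these, GSU2396, GSU2398, GSU2395 and GSU3579 lie together between 2628069 and 2631029. With the adjustment for local coverage 59 genes passed 2-fold. The simulation had no differences of coverage, so its 67 genes are a nearer counterpart of these 59 than of the 225. After the adjustment, the number beyond 2-fold was thus not above that from counting error alone. The 5 lowest then had −0.10, −0.25, −0.75, 0.19 and −0.24, in the order named.

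Fumarate and Fe(III) citrate were compared over 3336 genes, and 224 passed 2-fold, 174 higher and 50 lower on fumarate. The lowest were a run of adjacent efflux pump genes on the minus strand. GSU2135, GSU2136 and GSU2137, the inner membrane, membrane fusion and outer membrane parts of a pump of the resistance-nodulation-division (RND) family, had 108, 39 and 22 calls on Fe(III) citrate and 0 on fumarate. The fumarate table listed no position at all over them, so no fold is given. They were followed by GSU3598 (6 calls on fumarate and 18 on Fe(III) citrate, −2.23, interval −3.85 to −0.83) and by ppcD, the gene of a periplasmic cytochrome (6 and 15 calls, −1.97, interval −3.62 to −0.52). The highest were GSU2074 (60 and 1 calls, 5.26, interval 2.73 to 10.59), GSU2070 (20 and 1 calls, 3.68, interval 1.03 to 9.05), GSU1318 (19 and 1 calls, 3.604, interval 0.95 to 8.98), GSU2293 and the TRAP transporter gene GSU2056 (both 3.21, interval 1.23 to 6.33). All 5 had lower coverage on Fe(III) citrate, from 26 to 62.5 reads against 87 to 109. With the adjustment for local coverage these had 2.47, 2.78, 2.90, 2.12 and 2.04, GSU3598 had −1.35, and 63 genes passed 2-fold. Those 63 include GSU2135, GSU2136 and GSU2137, whose ratios could not be adjusted.

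HFO and fumarate had the fewest such genes at this score threshold, though not at a score over 100, where the 3 pairs had 734, 417 and 479. Of 3394 genes compared 68 passed 2-fold, 51 higher and 17 lower on HFO, and 15 did so after the adjustment for local coverage. Those 15 include the 5 highest genes, which kept their unadjusted ratios because fumarate had no coverage value there. The highest were again the pump genes GSU2135, GSU2136 and GSU2137, with 173, 78 and 63 calls on HFO, and their neighbours GSU2133 and GSU2132, with 35 and 30. All 5 lie where fumarate listed no position. The lowest were the transposase gene GSU2396 (20 and 44 calls, −1.63, interval −2.47 to −0.84), the potassium uptake gene GSU2350 (−1.51, interval −1.94 to −1.10), ptsP (100 and 187 calls, −1.40, interval −1.76 to −1.04), GSU2348 (−1.37) and GSU1164 (−1.34). Coverage of ptsP was 66 on HFO and 123 on fumarate, and with calls taken by an IPD ratio of at least 2 its ratio was 0.0081. Adjusted for local coverage, the 5 lowest had −0.29, −0.46, −0.083, −0.71 and −0.11.

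In each pair most genes of extracellular electron transfer had a ratio whose interval included 0. The exception with the largest value was omcZ, the gene of a cytochrome that forms conductive filaments, at 2281459 to 2282880. It had 8 calls on Fe(III) citrate, 130 on HFO and 61 on fumarate, log2 ratios of 2.88 (1.86 to 4.13) for HFO and 2.29 (1.22 to 3.56) for fumarate over Fe(III) citrate. Its median coverage was 44 on Fe(III) citrate against 121 and 96, and it lies just beyond GSU2074 and GSU2075. Adjusted for local coverage, its ratios were 0.83 and 0.68. The multicopper oxidase gene ompB had 0.66 (0.34 to 0.99) for HFO over Fe(III) citrate, and its counterpart ompC had −0.58 (−0.89 to −0.26). Adjusted for local coverage these were 0.27 and −0.18. The inner membrane cytochrome gene imcH had −0.61 (−1.02 to −0.19; −0.41 adjusted) in that pair, while cbcL, the other such gene, had −0.03 (−0.42 to 0.37). The surface cytochrome genes omcB and omcC had 0.00 and 0.05, and pilA, the pilin gene, had −0.88 (−1.79 to 0.06).

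The periplasmic cytochrome genes ppcB, ppcC and ppcD carried fewer calls on fumarate than on Fe(III) citrate. Their log2 ratios were −1.001 (−1.82 to −0.20), −1.45 (−2.44 to −0.52) and −1.97, on 25 against 32, 16 against 28 and 6 against 15 calls. Coverage of ppcB was also lower on fumarate, 87.5 against 108, and its ratio turned to 0.15 with the adjustment for local coverage, while those of ppcC and ppcD were −0.36 and −1.52. The genes ppcA and ppcE had −0.75 (−1.56 to 0.06) and 0.48 (−0.60 to 1.66). The cytochrome peroxidase gene macA had 0.85 (0.18 to 1.55; 0.37 adjusted) and omcS 0.76 (0.20 to 1.35; 0.32 adjusted) for fumarate over Fe(III) citrate, and omcS had −0.75 (−1.19 to −0.31) for HFO over fumarate, a ratio that turned to 0.079 with calls taken by IPD ratio and was −0.28 adjusted. For HFO over fumarate ppcC had 1.36 (0.55 to 2.26; 0.44 adjusted), ppcD 2.01 (0.74 to 3.55; 1.203 adjusted), omcZ 0.60 (0.15 to 1.06; 0.20 adjusted), ompC −0.47 (−0.75 to −0.19; −0.15 adjusted) and ompB 0.34 (0.09 to 0.60). The ompB ratio of that pair turned to −0.17 with calls by IPD ratio and to −0.036 with the adjustment for local coverage.

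The genes for fumarate use showed no common direction. The transporter gene dcuB, whose product exchanges fumarate and succinate, had 69 calls on Fe(III) citrate, 91 on HFO and 71 on fumarate, log2 ratios of −0.74 (−1.21 to −0.27) for HFO and −0.60 (−1.10 to −0.10) for fumarate over Fe(III) citrate. Adjusted for local coverage these were −0.24 and −0.26. The fumarate reductase genes frdA and frdB had 0.60 (0.21 to 1.00) and 0.57 (0.03 to 1.13) for HFO over fumarate, or 0.44 and 0.22 adjusted, and frdC had 0.09 (−0.61 to 0.81). The fumarate hydratase gene GSU0994 had intervals that included 0 in all 3 pairs. Of the genes named as DNA methyltransferase or restriction genes, GSU0227 and the type II restriction endonuclease gene GSU1365 had intervals that included 0 in all pairs. The third, rsmD, which by its symbol encodes a ribosomal RNA methyltransferase, had 0.86 (0.17 to 1.59) for fumarate over Fe(III) citrate and −0.63 (−1.15 to −0.11) for HFO over fumarate. The former turned to −0.12 with calls by IPD ratio and to −0.21 with the adjustment for local coverage, with which the latter was −0.46. None of these 3 genes held a GTACAG site.

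The stretch with no entry on fumarate ran from 2347384 to 2356663, 9280 bp in which Fe(III) citrate listed 508 positions and HFO 769. It held 10 whole genes, all on the minus strand: the pump genes GSU2135, GSU2136 and GSU2137, GSU2134 for a nitrogen regulatory protein of the P-II family, the lipoprotein gene GSU2133, and GSU2129, GSU3559, GSU2131, GSU2132 and GSU3560 for proteins of unknown function. The stretch began within the ISGsu7 transposase gene GSU2128, which runs from 2346547 to 2347437, and ended before another copy, GSU2140, at 2356993 to 2357883. Between 2357913 and 2358983, 1071 bp, fumarate again listed nothing while the others listed 56 and 81 positions. The next longest stretches without entries in fumarate were 1508 and 1446 bp, where the other libraries listed at most 3 positions.

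**Figure D4:**
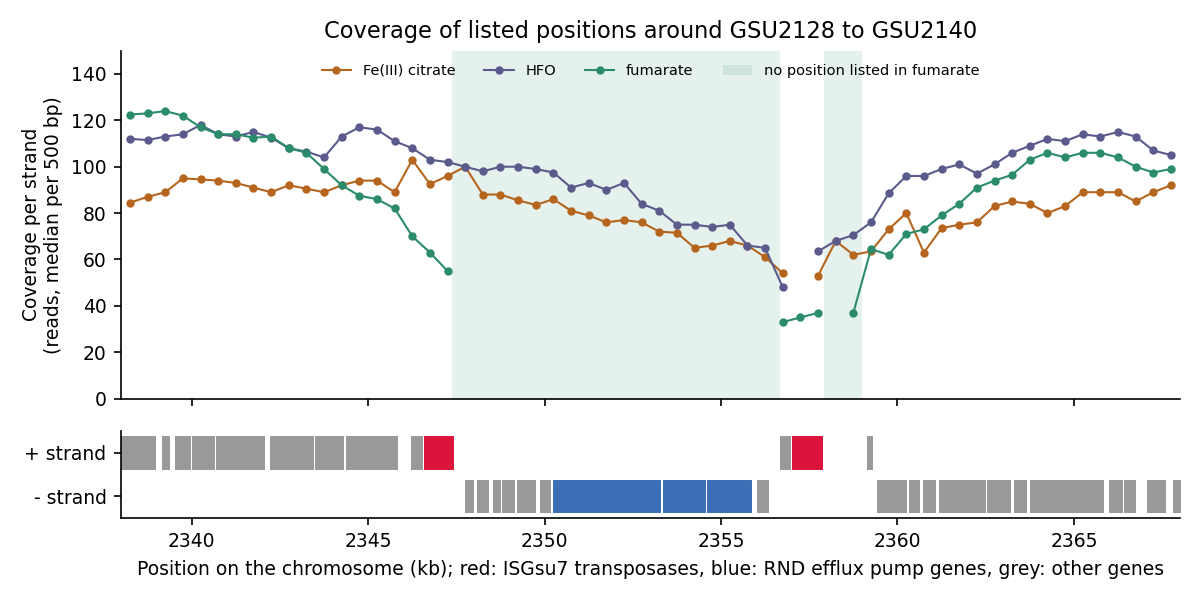
Median coverage per strand in reads (y axis, per 500 bp) of listed positions around GSU2128 to GSU2140 (x axis, position on the chromosome in kb) in the 3 libraries, with the genes of both strands below; shading marks the 9280 and 1071 bp without an entry on fumarate. In the 500 bp left of the shading, coverage over the library's median is 0.528 on fumarate, 0.919 on HFO and 1.15 on Fe(III) citrate.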

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

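The matched or adjusted local coverage and the removal of the genes of the stretch were tests chosen only after the result was seen; all others were planned. No paired analysis was possible because each acceptor had 1 library. Of the values that answer a comparison, 114 stayed within their counting interval or 1.5 times the count and 57 moved; of the ratios of named genes 981 stayed, 77 moved and 8 reversed, and of the group medians 419 stayed and 61 moved. Dropping the coverage minimum removed or added no call, so it tested nothing, and coverage over 50, gene bodies alone and scaling by the median ratio moved no value that answers a comparison beyond these limits. Ratios with fewer than 20 calls left gave no value, 59 of them at a score over 100 and 19 with calls by IPD ratio. Where no reason is given, the cause was not tested. Since the score grows with coverage, depth limits the numbers of m4C calls and the ratios of genes and gene groups: with the adjustment for local coverage, none of the 3 group ratios of the report stayed outside the central 95% of random lists.

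The score threshold set most counts. Over 100, m4C calls numbered 16170 (Fe(III) citrate), 78208 (HFO) and 43146 (fumarate), m6A calls 514, 717 and 712, and positions in all libraries 5270 (m4C) and 423 (m6A). GTACAG was then called at 65.2%, 87.5% and 85.7%, and 320 sites missed a library. With calls by an IPD ratio of at least 2 at a score over 20, m4C calls numbered 75961, 136678 and 90991, with 23041 in all libraries. The m6A calls then numbered 917 on HFO and 1255 on fumarate. Equal list lengths left 42400 m4C positions in all libraries, since the lists were shorter. Requiring a score under 20 or no entry in the other library left 6 GTACAG sites that differed. At local coverage within 5 of 100 the m4C shares were 8.97%, 12.9% and 9.40%.

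The upstream share of m4C stayed below the genome's in each setting run for it, which were the score and coverage thresholds, calls by IPD ratio, scaled scores and 2 other upstream lengths. Its ratio to the genome for Fe(III) citrate, HFO and fumarate was 0.715, 0.742 and 0.723 at a score over 20, 0.665, 0.695 and 0.672 over 40, 0.591, 0.590 and 0.596 over 100, and 0.749, 0.733 and 0.757 with calls by IPD ratio. With scaled scores it was 0.697 on HFO and 0.680 on fumarate, and for 100 bp upstream 0.701 and 0.677.

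Genes beyond 2-fold for HFO over Fe(III) citrate, fumarate over Fe(III) citrate and HFO over fumarate numbered 132, 113 and 37 at a score over 20, 362, 339 and 128 over 40, and 734, 417 and 479 over 100. They numbered 102 and 83 in the first 2 pairs with calls by IPD ratio, 120 for HFO over fumarate with scaled scores, and 59, 63 and 15 with the adjustment for local coverage. The 63 and the 15 include genes of the unlisted stretch, which could not be adjusted. Over 100, 5 group ratios lay outside the central 95% of random lists. Of the densities, 7 did with calls by IPD ratio and 6 with upstream sequence alone.

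Calls by IPD ratio reversed the log2 ratios of ptsP (0.0081), ompB (−0.17) and omcS (0.079) for HFO over fumarate and of rsmD (−0.12) for fumarate over Fe(III) citrate. The adjustment for local coverage reversed GSU2395 (0.19, HFO over Fe(III) citrate), ppcB (0.15) and rsmD (−0.21, both fumarate over Fe(III) citrate) and ompB (−0.036, HFO over fumarate).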

Other observations

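All tests in this part were chosen after the result was seen, except that of the expected kinetics of the sequence context.

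After adjustment for local coverage, 4 group ratios other than those of the report lay outside the central 95% of random lists. For HFO over Fe(III) citrate the genes matched by ribosomal protein had a median log2 ratio of −0.15 (percentile 0.44), those matched by type IV pilus terms 0.13 (percentile 97.6) and the efflux and heavy metal transport genes 0.07 (percentile 99.2). For HFO over fumarate the c-type cytochromes had 0.05 (percentile 99.5). All 4 medians were small, and chance alone puts 5% of the 48 ratios outside.

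Coverage itself varied along the chromosome. On Fe(III) citrate its median was 94 reads in the first 200 kb, 91 in the last and 78.5 at 1.8 to 2.0 Mb, while HFO had 112, 109.5 and 112.5 and fumarate 110, 108 and 105. Between 2278001 and 2280000, around GSU2074 and beside omcZ, the median was 27 on Fe(III) citrate, 99 on HFO and 85 on fumarate. The element ISGsu7 had 9 transposase genes, of which 6 had more than 10 listed positions in every library and 2, GSU2279 and GSU3083, had none in any. The remaining copy, GSU2140, had 23 listed positions on fumarate, at a median coverage of 37, and 0 on Fe(III) citrate and on HFO.

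Fumarate listed nothing over 9280 bp that hold the RND pump genes GSU2135, GSU2136 and GSU2137. Chance was excluded by the 130.3 positions expected at the coverage of the flanks, and unmappable sequence by the other libraries, which listed at least 0.64 of their genome-wide rate there. Entries left out of the table would leave the flanks at full coverage, but they had 0.528 and 0.604 of the fumarate median; on the left side, where Fe(III) citrate and HFO had 1.15 and 0.919, the fall was largest on fumarate, and on the right the others were low too (0.741 and 0.685). Recombination between GSU2128 and GSU2140 would keep the sequence after GSU2140, yet fumarate listed 0 positions there against 56 and 81. Loss of the segment next to GSU2128 in the fumarate culture may explain the pattern, as the stretch began 53 bp before the end of that gene. This is a hypothesis from 1 library, and whether growth on fumarate had a part was not tested. Between the unlisted parts fumarate listed 37 positions at a median coverage of 34. From 2356537 to 2357924, which includes GSU2140, Fe(III) citrate listed 0 positions and HFO 3. How reads were divided among the copies of ISGsu7 in each library was not tested.

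HFO had 2.22 times the m4C calls of Fe(III) citrate. Coverage did not account for all of it, since the ratio at matched local coverage was 1.435 (1.42 to 1.45) and lay between 1.38 and 1.56 at other coverages; for fumarate over Fe(III) citrate it was 1.048, so most of that excess went with coverage. At GTACAG sites IPD ratios were not higher on HFO, with a median ratio to Fe(III) citrate of 0.927 (0.913 to 0.943). These sites are methylated adenines, so they cannot exclude higher IPD ratios at cytosines in the HFO library. The oxalate step or another difference in preparation could have caused the rest and cannot be told apart from the acceptor with 1 library of each kind. An effect of the acceptor itself was not tested and stays open. The excess on HFO was absent among calls with an IPD ratio of 3 or more. Such calls made up 1.35% of the m4C calls on HFO against 3.36% on Fe(III) citrate.

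The m4C calls were scattered, with a median IPD ratio below 2, and no short word was called nearly everywhere: the highest share was 64.6%, at GGCGCC on HFO. An enzyme that methylates such a word at almost every occurrence stays open, since detection was incomplete: on Fe(III) citrate the share at GGCGCC was 31.2% at a coverage of at most 77 and 53.2% at 93 or more. The rise was smaller in the other libraries. On HFO the share was 59.6% at a coverage of at most 103 and 69.0% at 119 or more. On fumarate it was 51.0% at a coverage of at most 99 and 60.1% at 114 or more. Another candidate explanation is that the model set the expected kinetics of some contexts too low. A position called in 1 library was called in another 1.474 to 2.475 times as often as other places with the same 11 bases; at most 1.1 was set as the mark of this explanation and over 1.5 in every pair and window as the mark against it, and 4 of the 6 ratios passed 1.5. The other places were called at 20.9% or 14.2% on Fe(III) citrate after a call on HFO, depending on the window, against 6.60% of all cytosines, so the local bases carried part of the recurrence, and whether wider context or methylation carried the rest cannot be told apart here.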
